A study of Danio rerio with 18 samples.

How the data were processed

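The samples were pools of whole zebrafish embryos, each hybridised to a one-colour NimbleGen expression array. There were 18 arrays in 6 groups of 3, made up of unexposed controls, embryos in 50 µg/mL of MES particles and embryos in 10 µg/mL of TMAT particles, each collected at 24 and at 48 hours post fertilization (hpf). Each sample pooled 40 embryos, which were dechorionated at 4 hpf and exposed from 6 hpf. Both particles are gold nanoparticles with a 1.5 nm core. MES stands for mercaptoethanesulfonate, an anionic ligand, and TMAT for trimethylammoniumethanethiol, a cationic one. The sources used here do not say whether the pools came from separate clutches. The p-values of features and of array scores therefore measure the spread between these pools and no wider spread.

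The authors deposited 1 table per array with an intensity for each feature on a linear scale. The submitters' processing notes name RMA, which comprises background correction, quantile normalization and a summary over probes. The version of the software is not given in the sources used here, nor is it stated whether the arrays of both ages were normalized together. The mean difference between the quantiles of 2 arrays was 0.0752 on the log2 scale for arrays of the same age and 0.105 for arrays of different ages. The authors also deposited a combined table of the same intensity values. Every one of its 18 columns equalled one of the per-array tables (tolerance 0.001), but 2 equalled the table of the sample they were labelled with and 16 equalled that of another sample. Of the 18 columns, 10 had the same age and 6 the same agent by both labels. The per-array labels were checked on ampd1, the named gene with the largest rise between ages in controls. By these labels its mean log2 intensity was 8.27 to 8.46 in the 3 groups at 24 hpf. It was 14.92 to 15.00 in the 3 groups at 48 hpf (SD at most 0.68). The per-array labels therefore separate the ages in exposed arrays too, which had no part in choosing the gene. The combined table's labels give 8 columns the other age. In the column order of the combined table the per-array labels ran through controls, then MES, then TMAT particles. Within each of these, the replicates ran from 1 to 3 with 24 and 48 hpf alternating. So regular an order argues against agents being mixed up in the per-array labels. Which labels of agent are right is not stated in the sources used here, and the particle comparisons rest on those of the per-array tables. The per-array tables were used, and the combined table with its columns as labelled was run as an alternative.

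The log2 of each intensity was taken with no further normalization and no pseudocount. A feature summarised a median of 8 probes (1 to 12), and 37105 features were tested after the single control feature of 3342 random probes was set aside as a measure of background. The features carried identifiers of several old annotations, with 11273 OTTDART, 10119 ENSDART, 6754 ZV700S, 3779 TC, 3051 RefSeq and 2129 others. A current gene symbol was available through RefSeq for 2659 features (2646 symbols), and 392 RefSeq identifiers had no match. The genome position of each probe was not used here. Counts are therefore of features, and named genes come from the small part with a symbol.

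Differential expression was tested with limma 3.58.1 in R 4.3.3. One fit held the mean of each of the 6 groups (12 residual degrees of freedom, 3.85 prior degrees of freedom), with 9 two-sided contrasts and 2 moderated F tests of any particle effect at an age. P-values were adjusted over all features by the Benjamini-Hochberg method, separately for each contrast, and an adjusted p of 0.05 was the threshold for a call. The contrasts were each particle against the control of its age, TMAT against MES particles at each age, the change of each particle's effect between the ages, and 48 against 24 hpf in controls. The number of arrays limits the precision: the median standard error of a log2 difference was 0.327, and 0.463 for a change of effect between ages.

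The tests, the rule for naming genes, 32 gene lists and most alternatives were chosen before the data were examined. For particles against controls and for 48 against 24 hpf in controls, the rule took the 12 largest rises and the 12 largest falls among called features with an informative symbol and no overlap between the 3 and 3 values. Where none was called it took the 6 smallest p-values in each direction, among features with an informative symbol. It also took up to 4 members of each list described, by smallest p. The comparison of the particles used the same rule with 6 genes each way. A gene taken by this rule is not reported here. The lists held 1742 symbols, of which 1694 had a current name and 211 were measured. The 23 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Camera compares a list with other genes, so its p-value at the preset correlation does not measure the spread between pools. Lists were also adjusted alone, over their own members. The similarity of both particles' effects was set against simulations (20) in which the particles shared controls and had no effect.

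A developmental axis was drawn for each particle from the 24 to 48 hpf change of the other particle's arrays, over the features past the threshold in that change, and scores were compared with a two-sided exact permutation test. With 3 against 3 arrays that test cannot give a p below 0.1.

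The steps were tested on simulated data with independent noise in each feature, at the SD of that feature pooled over all 6 groups. The larger spread of the controls and deviations common to a whole array were not simulated. Of 100 features raised or lowered 4-fold, 60% were recovered for MES particles at 48 hpf, 65% for TMAT particles at 24 hpf and 62% for controls between ages. At 2-fold the shares were 9%, 17% and 7%. False calls made up 5.5%, 3.5% and 8% of the calls in these simulations. For the change of the MES effect between ages, 33.5% of 4-fold changes were recovered. A simulated list shift was called in each comparison tried, with 0 other lists called. Features were independent there, so this does not test camera on genes that vary together.

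The alternatives were the combined table, repeated quantile normalization, median-centring, filters on low values, array weights, an intensity trend with a robust prior, an ordinary unmoderated statistic, arrays of one age only, the replicate number as a block, other thresholds, another test for the lists and leaving out each array in turn.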

Results

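Gene expression was measured in whole zebrafish embryos exposed to gold nanoparticles that differed in surface ligand, and in unexposed controls. There were 3 arrays for each of 6 groups: controls, MES particles (50 µg/mL) and TMAT particles (10 µg/mL) at 24 hpf, and the same at 48 hpf. The series title gives the question as how surface functionality affects embryonic gene expression. Each array gave RMA intensities for 37105 features. The median intensity of an array lay between 1809 and 2197.

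The control arrays varied more than the exposed ones. The mean correlation across features within a group was 0.913 in 24 hpf controls and 0.933 in 48 hpf controls, against 0.972 and 0.959 in MES and TMAT embryos at 24 hpf and 0.982 and 0.981 at 48 hpf. Features are not independent replicates, so these values only describe the arrays. The median residual SD was 0.48 and 0.42 in the control groups (log2 scale, n = 3 each) and 0.21 to 0.33 in the exposed groups. The intensity of random control probes, which match no zebrafish sequence by design, was 106, 169 and 82.8 in control arrays 1, 2 and 3 at 48 hpf, and 99.5, 126 and 84.4 at 24 hpf. It was 78.8 to 96.4 in the 12 exposed arrays. Control array 1 at 24 hpf and control array 2 at 48 hpf had the lowest mean correlation with other arrays of their age, 0.885 and 0.881.

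**Figure D1:**
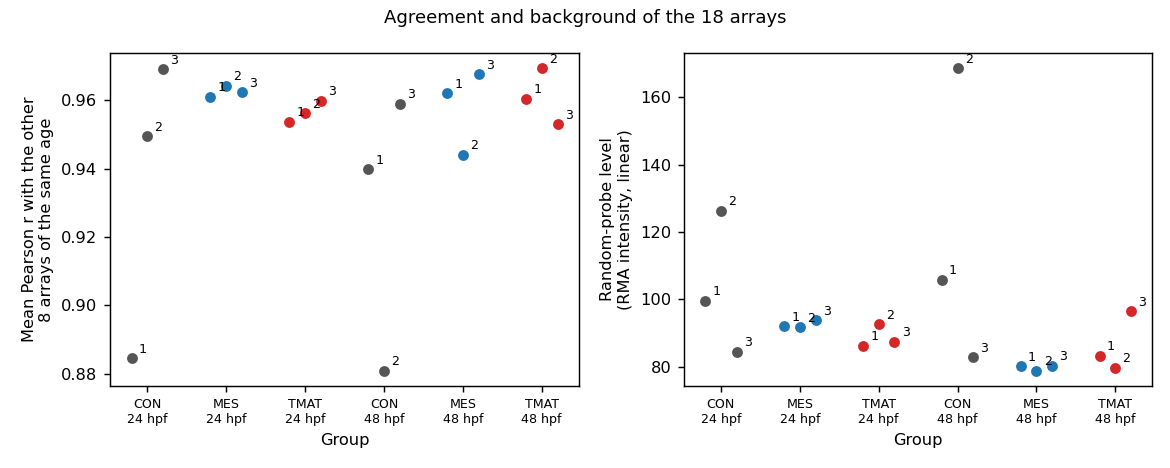
Mean correlation (r across features) of each array with the other arrays of its age, and the intensity of its random control probes, by group with replicate numbers marked. Control array 2 at 48 hpf has the highest random-probe intensity (169) and the lowest mean r (0.881).

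The 48 against 24 hpf comparison of controls shows the normal change over this day of development. The largest named rises included single genes known from muscle, the lens, cartilage and the synapse. The largest named falls included single genes known from early patterning and also from muscle. The largest named rise was in ampd1, the AMP deaminase of muscle (NM_200893, log2 fold change 6.57 ± 0.28 SE, adjusted p = 2.05e-09, n = 3 per age, limma). The gamma M2 crystallins crygm2d17, crygm2d20 and crygm2d13, structural proteins of the lens fibre, rose by 5.85, 5.09 and 3.90, and lim2.5, a lens fibre membrane protein, by 4.84. The troponin tnni2b.2 of fast muscle rose by 4.27, the muscle protease gene capn3a by 3.87, the cartilage matrix gene matn3a by 4.21, the claudin cldn7a by 3.71, and syt5b, bhlhe23 and the synaptic adhesion gene nrxn3b by 4.08, 3.81 and 3.70. Among the falls were prtga (−2.98), the hairy-related repressors her3 (−2.86) and her12 (−2.14), the blood zinc-finger gene blf (−2.71), smtnl1 (−2.65) and oc90, a protein of the otoliths (−2.59). The other falls named by the rule were wfikkn1, tm6sf2a, dhrs7ca, mmp30, emg1 and pth1b, from −2.44 to −2.16. In total 9942 of 37105 features were called, 4954 higher and 4988 lower at 48 hpf. Of these, 844 had a gene symbol, 513 of them higher.

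Camera called 4 of the 23 lists fixed in advance and large enough to test, of which the neuronal list held with an estimated correlation. Of 25 measured lens genes 19 rose, 0 fell and 6 did not pass (median 2.29, camera adjusted p = 1.30e-09). That call was lost with the correlation between lens genes taken from the data (adjusted p = 0.212 with an estimated correlation). Of 11 neuronal genes 8 rose (9 adjusted over the list alone) and none of the 11 had a negative value. They included the NMDA receptor subunit grin1a (3.30 ± 0.33), the glycine transporter slc6a5 (2.47 ± 0.29) and the vesicular glutamate transporter slc17a6a (2.81 ± 0.38). This list was called (adjusted p = 0.000119) and held (adjusted p = 0.0133 with an estimated correlation). Of 10 photoreceptor and retina genes 4 rose (5 adjusted over the list alone), with the arrestin sagb at 3.70, its relative saga, retinoschisin rs1a at 3.61 and the phosphodiesterase subunit pde6hb at 1.26. The list had an adjusted p of 0.0356, lost at adjusted p = 0.425 with an estimated correlation. Of 5 cell-cycle genes 2 fell (3 adjusted over the list alone), ube2c by −1.44 and the chromatin assembly gene chaf1a by −1.21. The median was −0.99 and the adjusted p 0.0356, against adjusted p = 0.212 with an estimated correlation. The photoreceptor and cell-cycle calls were lost without control array 2 at 24 hpf (0.206 and 0.0888), without control array 3 at 24 hpf (0.135 for both) and without control array 2 at 48 hpf (0.0509 for both). The lens and neuronal calls held without each control array. The fry test, which does not compare a list with other genes, called 10 of the 23 lists, among them skeletal muscle (6 of 14 members rose and 2 fell, fry adjusted p = 2.95e-10, camera adjusted p = 0.164). Of 4 circadian clock genes, too few for a list test, per1b (1.93), rorca (1.62) and per3 (1.24) rose, and hlfa, at 0.79 ± 0.34, did not pass. All 4 passed when adjusted over the list alone. The call of per3 was lost without control array 1 or 2 of either age (adjusted p from 0.0636 to 0.148), that of rorca without control array 2 at 48 hpf (0.0543) and that of pde6hb without control array 2 of either age (0.0647 and 0.0777), while hlfa passed without control array 2 at 24 hpf (0.0333). Centring each array on its median moved the share of calls that were higher from 49.8% to 40.4%.

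In embryos exposed to MES particles, 48 hpf was the age with called differences from controls. The lens gene crygm2a, the peptide hormone genes avp and npffl and the egg-coat gene zp3.2 were higher, and the receptor genes adcyap1r1a and grin1a and the axon guidance gene sema6d were lower. The gamma crystallin crygm2a (NM_001018121) rose by 2.84 ± 0.62 SE (11.18 ± 1.34 against 8.35 ± 0.46, mean log2 intensity ± SD, n = 3 per group, limma adjusted p = 0.0250). Its relatives crygm2d4 and crygm2b rose by 2.63 and 1.86. These crystallin genes are close paralogs, and whether each feature reads its own gene was not tested. The neurohypophysial hormone gene avp (NM_178293) rose by 2.31 ± 0.45 (adjusted p = 0.0237) and the neuropeptide gene npffl (NM_183346) by 2.19 ± 0.48 (adjusted p = 0.0253). The largest named rise was trappc2l (NM_001003506), a member of a vesicle tethering family (2.93 ± 0.56, adjusted p = 0.0237, a feature of 3 probes). Other rises included the methionine sulfoxide reductase msrb2 (2.01), the egg-coat gene zp3.2 (1.65), the taste receptor tas2r200.1 (1.69), the protocadherin pcdh2aa3 (1.67) and xkr4 (1.66).

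Among the falls with MES particles at 48 hpf, adcyap1r1a (NM_001013444), a receptor for the neuropeptide PACAP, fell by −2.13 ± 0.33 (9.63 ± 0.57 against 11.76 ± 0.53, n = 3 per group, limma adjusted p = 0.0175). The axon guidance gene sema6d (NM_001017682) fell by −1.67 ± 0.26 (adjusted p = 0.0175) and the receptor phosphatase ptprdb by −1.56. The NMDA receptor subunit grin1a fell by −1.32 ± 0.33 (adjusted p = 0.0345). The small Maf gene mafga fell by −1.41, the potassium channel kcnj11 by −1.35, vgll2a by −1.48, the apoptosis gene pmaip1 by −1.52, the ubiquitin ligase rnf114 by −1.51 and the lipid droplet gene cidec by −1.37. The genes phlda1 and lrrc30a fell by −1.35 and −1.34. From the list of red blood cell genes, the haem synthesis enzyme ppox fell by −1.19 ± 0.29 (adjusted p = 0.0301), 1 of 8 members.

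In total limma called 2138 features for MES particles at 48 hpf, 1437 higher (median 1.93) and 701 lower (median −1.23). The balance was the reverse among the 86 called features with a gene symbol, of which 30 were higher and 56 lower. With gene-by-gene array weights the balance over all features turned as well, with 7038 higher and 12065 lower. The median over all features was −0.14, and −0.15 for TMAT particles at 48 hpf, so a change relative to the typical feature is that much larger for a rise and smaller for a fall. The calls rested on single arrays of both groups. Without control array 1 limma called 0 features, without control array 2 it called 2, and without control array 3 it called 6260. Leaving out MES array 1 or MES array 2 gave 0 calls, and leaving out MES array 3 gave 2275. The ordinary statistic called 0, with 8721 features at an unadjusted p under 0.05 in limma (1855 by chance).

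**Figure D2:**
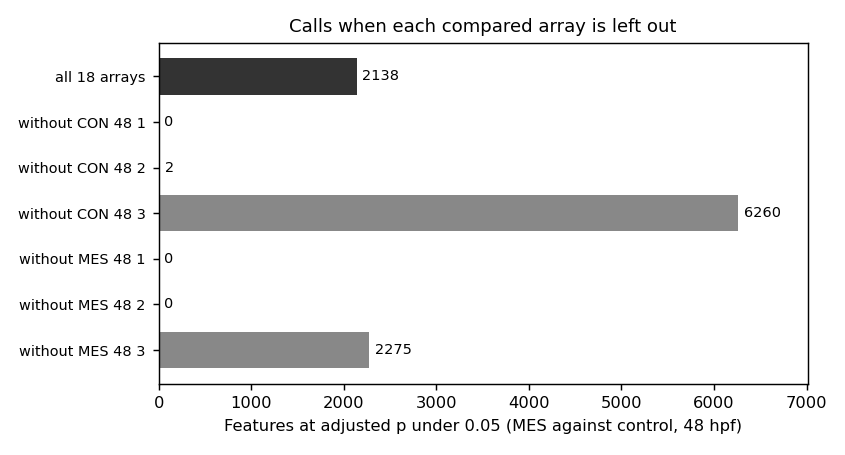
Number of features called for MES particles at 48 hpf (adjusted p of 0.05, limma) with all arrays and with each array left out in turn. The count ranges from 0 to 6260, and the highest bar is that without control array 3.

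**Figure D3:**
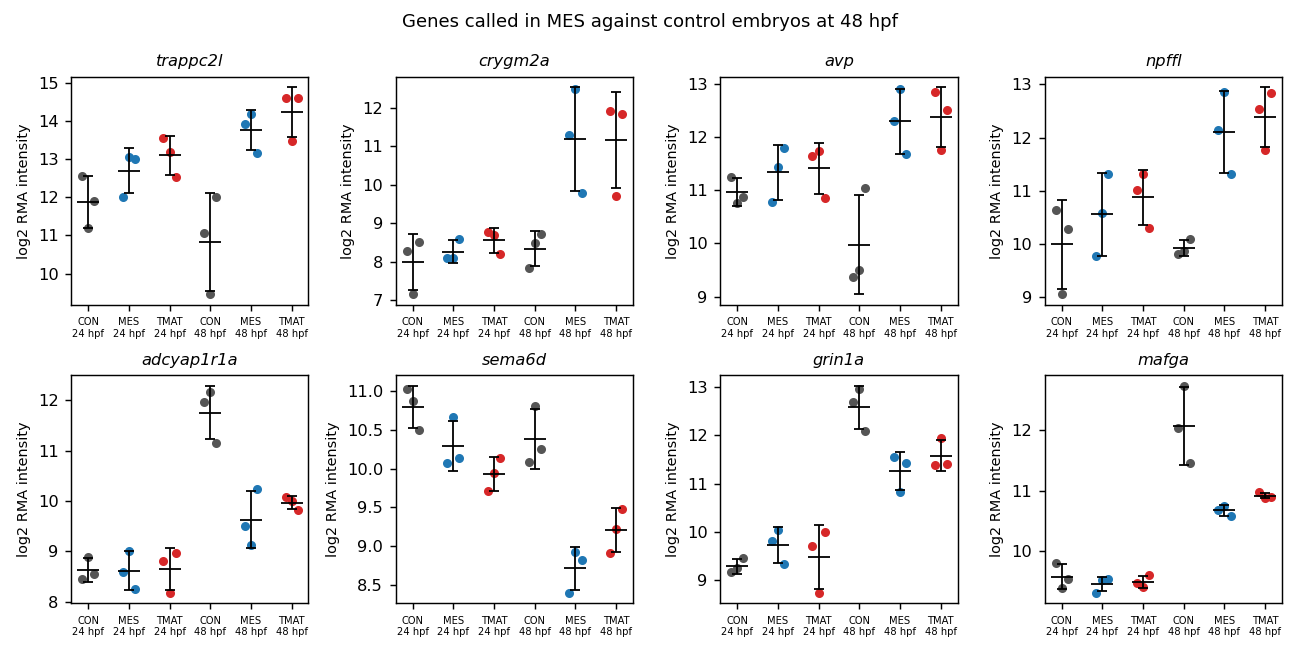
Log2 RMA intensity of 8 genes in each group, with a point per array and the mean ± SD (n = 3). At 48 hpf trappc2l, crygm2a, avp and npffl are higher, and adcyap1r1a, sema6d, grin1a and mafga lower, in MES embryos than in controls, and TMAT embryos lie near MES embryos.

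By list, 3 of 25 lens genes rose with MES particles at 48 hpf, 0 fell and 22 did not pass, with a median of 0.25 and 18 positive values (camera adjusted p = 0.000312). The call was lost at adjusted p = 0.918 with an estimated correlation, and also when those 3 crystallins were left out (adjusted p = 0.0761). Without control arrays 1 and 2, whose random-probe intensity was 106 and 169 at 48 hpf, the lens list had an adjusted p of 0.0631. Of 11 neuronal genes 2 fell, grin1a among them, both also when adjusted over the list alone, and slc17a6a was at −1.04 (adjusted p = 0.111). The list's median of −0.19 was near the median of all features, and camera did not call it (adjusted p = 0.864), while fry did (adjusted p = 0.00845). Of 6 complement and acute-phase genes 1 rose, the complement gene c3a.2 (1.39 ± 0.38, adjusted p = 0.0442), and the list did not pass (adjusted p = 0.261). All 5 genes of early patterning had negative values (median −0.91), among them hoxc13b (−0.92), wnt3a (−1.45) and ripply1 (−0.91). None passed over all features, 3 passed adjusted over the list alone, and the list had an adjusted p of 0.261.

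Lists chosen for particle toxicity were not called with MES particles at 48 hpf. Camera adjusted p was 0.975 for heat shock genes (6 measured), 0.261 for oxidative stress genes (5), 0.975 for metal response genes (5) and 0.975 for inflammation genes (6). Within them hmox1b, a haem oxygenase, was at 0.83 ± 0.29 (adjusted p = 0.0934), the glutathione transferase gstp1.1 at 1.11 ± 0.43 (adjusted p = 0.133) and the cytokine il1b at −0.40 ± 0.29 (adjusted p = 0.439). Of 3 apoptosis genes, too few for a list test, pmaip1 fell and casp3b was at −0.48 (adjusted p = 0.486).

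For TMAT particles at 48 hpf no feature was called, and several of the genes with the smallest p were among those named for MES particles. The smallest adjusted p was 0.0649, shared by trappc2l (3.40 ± 0.56 SE, n = 3 per group, limma), crygm2a (2.81 ± 0.62), npffl (2.46 ± 0.48), avp (2.39 ± 0.45) and c3a.2 (1.80 ± 0.38) on the higher side. The epithelial calcium channel trpv6, a gene of ion-transporting skin cells, was at 1.22 ± 0.25 with the same adjusted p. On the lower side were adcyap1r1a (−1.79), tpra1 (−1.49), the opioid peptide gene pdyn (−1.22), mafga (−1.16) and smtnl1 (−1.08), again at 0.0649. Limma called 0 features and the ordinary statistic 1, with 7519 at an unadjusted p under 0.05 and 1482 at an adjusted p of 0.1. Without control array 3, which had the lowest random-probe intensity of the controls, limma called 6310.

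Of the lists, lens genes passed for TMAT particles at 48 hpf by camera (median 0.12, 14 of 25 positive, adjusted p = 0.00607, but adjusted p = 0.848 with an estimated correlation). Without crygm2a, crygm2b and crygm2d4 the lens list did not pass (adjusted p = 0.208). Adjusted over the list alone, 3 lens genes passed as higher and 1 as lower. Complement and acute-phase genes passed as well (median 0.29, 5 of 6 positive, adjusted p = 0.0117, against adjusted p = 0.128 with an estimated correlation), with c3a.2 the 1 member to pass adjusted over the list alone. Without control array 2, whose random-probe intensity was 169, the complement list had an adjusted p of 0.0540. Both lists failed without control arrays 1 and 2 (adjusted p of 0.207 and 0.256). Of 11 neuronal genes 0 passed over all features and 2 passed as lower adjusted over the list alone (median −0.18, camera adjusted p = 0.996).

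At 24 hpf neither particle gave a called feature. For TMAT particles the smallest adjusted p was 0.654. The genes with the smallest p on the higher side were nrxn3b (0.91 ± 0.25 SE, n = 3 per group), c3a.2 (0.99 ± 0.38), ggact.1 (0.79 ± 0.30), wwtr1 (1.73 ± 0.67), bach1a (0.93 ± 0.38) and vgll2a (0.83 ± 0.34). On the lower side were ndufs8b, a subunit of respiratory complex I (−0.93 ± 0.28), map1lc3c (−0.90 ± 0.28), sema6d (−0.87 ± 0.26), stoml3a (−0.77 ± 0.20), the small heat shock gene hspb2 (−0.71 ± 0.21) and the secretogranin scg2b (−0.53 ± 0.16). For MES particles the smallest adjusted p was 0.787. Higher values were those of nrxn3b (0.81 ± 0.25), usp9 (1.84 ± 0.72), the clock gene per1b (1.22 ± 0.48), the muscle factor mef2ca (1.11 ± 0.42), ints2 (1.06 ± 0.35) and vgll2a (0.89 ± 0.34). Lower values were those of map1lc3c (−0.92 ± 0.28), rprml (−0.89 ± 0.23), the elastin elnb (−0.89 ± 0.24), ndufs8b (−0.87 ± 0.28), mybpc1 (−0.69 ± 0.22) and stoml3a (−0.63 ± 0.20). Limma and the ordinary statistic each called 0 features for either particle, and 2242 (TMAT) and 1459 (MES) had an unadjusted p under 0.05, against 1855 by chance.

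At 24 hpf camera called 2 lists for MES particles, and fry called 0. Lens genes were lower as a list (median −0.25, 23 of 25 negative, camera adjusted p = 0.0118, but adjusted p = 0.845 with an estimated correlation), with 0 members passing adjusted over the list alone. The direction depended on control array 1, the array with a mean r of 0.885. Without it the test pointed the other way (adjusted p = 0.884). Pigment cell genes were higher as a list (median 0.63, 6 of 7 positive, adjusted p = 0.0213, against adjusted p = 0.845 with an estimated correlation). Their values included the melanosome gene pmela (2.26 ± 0.90), gart (0.69 ± 0.40) and slc24a5 (0.63 ± 0.41), 0 of 7 passing adjusted over the list alone. The pigment call was lost without control array 1 (adjusted p = 0.148), without control array 3 (0.0732) and without MES array 3 (0.117). With TMAT particles the lens list had a median of −0.38 with 21 of 25 negative (adjusted p = 0.0815) and the pigment list a median of 0.39 (adjusted p = 0.117). With all arrays 0 lists were called for TMAT particles at 24 hpf, and 1 list was called without control array 2, without control array 3 or without TMAT array 2.

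**Figure D4:**
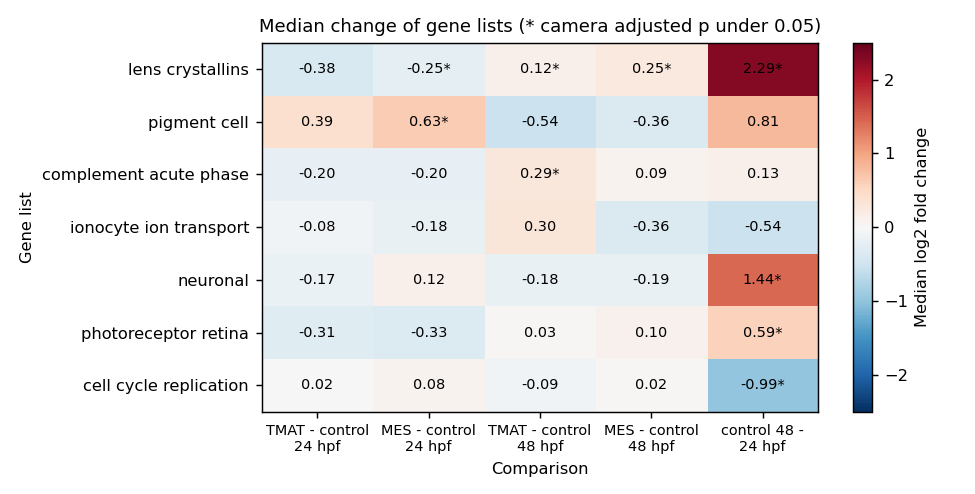
Median log2 fold change of 7 gene lists in each particle comparison and in controls between ages, with an asterisk where camera gave an adjusted p under 0.05. The lens list has medians of −0.38 and −0.25 at 24 hpf, 0.12 and 0.25 at 48 hpf and 2.29 between ages in controls.

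The particles were compared directly at each age, but at different doses (10 and 50 µg/mL), so ligand and dose changed together. At 48 hpf trpv6 (NM_001001849) was 1.18 ± 0.25 SE higher with TMAT than with MES particles (95% interval 0.65 to 1.72, n = 3 per group, limma adjusted p = 1.00). The other high values were those of the glutamate decarboxylase gad3 (1.14), the ammonia transporter rhcga (0.86), the claudin cldn5a (0.80), arid6 (0.72) and tspan5b (0.71). Lower with TMAT particles were the egg-coat genes zp2.3 (−1.08), zp3.2 (−0.98) and zp2.2 (−0.88), adenosine deaminase ada (−1.09), the odorant receptor or30bu1 (−0.76) and the nicotinic receptor subunit chrna4b (−0.68). None of these passed. As a list, ion transport genes of ionocytes were higher with TMAT particles (median 0.23, 5 of 5 positive, camera adjusted p = 0.000387), and the call held (adjusted p = 0.0203 with an estimated correlation). Of its members trpv6 and rhcga passed adjusted over the list alone and 0 passed over all features. The list was called without each array of either particle in turn, with adjusted p up to 0.0109, and was not called by fry (adjusted p = 0.0638). In controls trpv6 fell between 24 and 48 hpf, from a mean log2 intensity of 11.81 ± 0.22 SD (adjusted p = 0.00860). At 48 hpf its mean log2 intensity was 12.04 ± 0.17 SD in TMAT, 10.86 ± 0.18 in MES and 10.82 ± 0.38 in control embryos.

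Limma called 0 features between the particles at 48 hpf (590 at an unadjusted p under 0.05, 0 by the ordinary statistic) and 0 at 24 hpf (37 at an unadjusted p under 0.05, 0 by the ordinary statistic). Both unadjusted counts were below the 1855 given by chance. This does not show that the particles act alike. The median 95% interval reached 0.69 to either side, and it lay within a 2-fold difference for 61.3% of features at 48 hpf and 69.1% at 24 hpf. These intervals use a spread common to all 6 groups. The controls varied more (median SD 0.48 and 0.42) than the exposed groups (0.21 to 0.33). The standard errors therefore include control spread that has no part in comparing the particles. At 24 hpf the values with the smallest p were fut9b.3 (0.51), the lipoxygenase alox5b.3 (0.65), crygm2d17 (0.61), ms4a17a.16 (0.82), slc25a47a (0.31) and plod2 (0.50) on the higher side with TMAT particles. On the lower side were sat1a.1 (−0.51), cbln9 (−0.45), the crystallin crygn2 (−0.44), hspb2 (−0.37), kctd15b (−0.36) and rack1 (−0.28).

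The change of each particle's effect between 24 and 48 hpf was tested as an interaction. By camera the lens list changed upward as a list with both particles, with 0 of 25 members passing. The median change was 0.58 for MES (22 of 25 positive, camera adjusted p = 1.55e-06) and 0.46 for TMAT particles (21 of 25 positive, adjusted p = 6.39e-06). Both calls were lost (adjusted p = 0.824 and adjusted p = 0.539 with an estimated correlation), and both without control arrays 1 and 2 (0.257 and 0.453). The widest values were those of crygm2d4 (3.25 ± 0.91 MES and 2.90 ± 0.91 TMAT), with adjusted p of 0.193 and 0.610. Photoreceptor and retina genes passed for MES particles (median 0.54, 8 of 10 positive, adjusted p = 0.0415, against adjusted p = 0.824 with an estimated correlation), rs1a being at 1.28 ± 0.56. That call was lost without control array 1 at 24 hpf (0.685), MES array 2 or 3 at 24 hpf (0.147 and 0.0569), control array 3 at 48 hpf (0.138) or MES array 3 at 48 hpf (0.113). Of 11 neuronal genes 3 passed as lower adjusted over the list alone for MES particles, among them grin1a at −1.76 ± 0.47 and slc17a6a at −1.51 ± 0.53, and 0 passed over all features.

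Over all features 1 was called for the MES interaction, the unnamed transcript OTTDART00000029927. It stood at 0.54 against controls at 24 hpf and fell at 48 hpf (−2.25, adjusted p = 0.00895), a change of −2.79 ± 0.37 SE (adjusted p = 0.0487). It was singled out after its values were seen, and its TMAT interaction was −1.68 (adjusted p = 0.610). At an unadjusted p under 0.05 there were 5960 features for MES and 2772 for TMAT particles, of which limma called 0 for TMAT, and the ordinary statistic called 0 for both. The MES count was 1800 without control array 2 at 24 hpf, 929 without control array 3 at 48 hpf, and 0 without any other single array of these groups. The moderated F test of any particle effect called 696 features at 48 hpf and 0 at 24 hpf. The count at 48 hpf was 4895 without control array 3, 1274 without MES array 3, 2 without TMAT array 1 and 0 without any other single array of that age.

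Both particles were set against the same control arrays, and their effects ran in parallel across features. At 48 hpf 2406 features were higher and 3149 lower with both particles at an unadjusted p under 0.05, where independence would give 320 and 581. The correlation of the effects across features was 0.916, against 0.785 in simulations with shared controls and no particle effect, and 5555 features passed with both against 1863 simulated. At 24 hpf 237 were higher and 568 lower with both, the correlation was 0.900 against 0.711 simulated, and 805 features passed with both against 1577 simulated. At an adjusted p of 0.05 the particles shared 0 calls at either age. These counts were not repeated with the control arrays divided between the particles. The simulated counts came from fits to the arrays of a single age, and the real counts from the fit over both ages. Their error estimates differ, so the real and simulated overlaps cannot be compared. The simulations drew each feature independently, so they held no deviation common to a whole array. The correlation lay above the simulated value at both ages. Without such deviations, the simulations cannot tell a shared particle effect from control arrays that deviate as a whole.

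The position of exposed embryos along normal development was scored on the 24 to 48 hpf change of the other particle's arrays, where 0 is the 24 hpf control mean. TMAT embryos scored 0.149 above controls at 48 hpf (0.796 ± 0.094 against 0.648 ± 0.018, mean ± SD, n = 3 each, two-sided exact permutation p = 0.1, the smallest this design allows). At 24 hpf they scored 0.00932 above controls (exact p = 1), and this sign changed without control array 2 (−0.0902), MES array 3 (−0.0480) or TMAT array 1 (−0.0506). MES embryos scored 0.00899 above controls at 48 hpf (exact p = 0.7), a sign that changed without control array 2 (−0.00509), TMAT array 1 (−0.0149) or TMAT array 3 (−0.0111). They scored −0.0541 at 24 hpf (exact p = 0.1). The MES score at 48 hpf was 0.163 when all features were used in place of those past the threshold. A shift at 48 hpf that both particles share enters the axis, since each axis comes from exposed arrays.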

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

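Of the tests here, the random-probe covariate and the comparisons without control arrays 1 and 2 were chosen only after the arrays had been seen. A rule on spread was added after the lens medians had been seen. By it, a lens median that is small against its members' interquartile range decides nothing.

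The change of a particle's effect between 24 and 48 hpf was called by camera, which ranks a list against other genes, for the lens list with each particle and for the photoreceptor and retina list with MES particles, and by limma for 1 transcript. The lens list had a median change of 0.46 with TMAT particles and 0.58 with MES particles, and the photoreceptor and retina list 0.54 with MES particles. All 3 calls were lost with an estimated correlation (adjusted p = 0.539, 0.824 and 0.824) and without control arrays 1 and 2 (0.453, 0.257 and 0.257), and fry, which tests a list against no change, called none of them (0.451, 0.477 and 0.477). The transcript OTTDART00000029927 changed by −2.79 with MES particles, and it was the 1 call of that comparison.

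The 2138 calls for MES particles at 48 hpf came with control arrays that differed from each other, the median log2 shift signed by the direction of the call being 1.75, 2.01 and 1.14 against control arrays 1, 2 and 3, with the sign kept against control array 3 in 100% and a median of 0.78 for TMAT arrays against that array. Over the 6260 features called without control array 3, TMAT arrays kept a median share of 0.225 (quartiles 0.0355 and 0.399, 79.4% with the same sign) of the MES shift when set against control array 3, under the bound of 0.25 set in advance by less than this spread. A difference of control arrays 1 and 2 from control array 3 may therefore account for part of the calls. Selecting features against those arrays itself lowers the share. This grouping follows the random-probe intensity, and correlation does not give it. At 48 hpf the mean r with the other controls was 0.955, 0.917 and 0.927 for control arrays 1, 2 and 3. At 24 hpf it was 0.885, 0.920 and 0.933. The 100% and the 0.78 of TMAT arrays come from calls chosen with control array 3 among the controls. That choice itself favours a shift against control array 3, so these values cannot decide the question. With the log2 random-probe level of each array as a covariate limma called 0 features, and the median signed change of the 2138 went from 1.65 to 1.18, a ratio of 0.713, while the median SE went from 0.402 to 0.439, so a smaller change and a wider error ended the calls together. Background and particle effect cannot be told apart, because the mean log2 random-probe level was 6.83 in controls and 6.32 in MES embryos at 48 hpf, and an effect common to both particles stays open as untested.

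The lens list had a negative median with both particles at 24 hpf and a positive one at 48 hpf. The effect of a change of developmental stage was predicted from features outside the lens. It would give 1.70 times the observed lens median at 48 hpf for MES particles and 4.04 times for TMAT particles. These ratios met the bound set in advance for a stage difference, but they cannot show one. Each slope used the change in the other particle's arrays, so a shift shared by both particles enters it. At 48 hpf the slopes were 0.522 (MES) and 0.412 (TMAT) over features not past the axis threshold. Over those past it they were 0.00899 and 0.149. At 24 hpf the ratios were 0.590 for MES and −0.0675, the other sign, for TMAT particles. With slopes from the axis features alone the ratios at 48 hpf were 0.0936 for MES and 3.32 for TMAT particles. The lens medians of 0.25 and 0.12 were small against the interquartile ranges of 0.51 and 0.57. For MES particles the median met the rule on spread only narrowly. Members went both ways, 18 higher and 7 lower with MES, 14 higher and 11 lower with TMAT particles. Stage and a lens effect cannot be told apart. Against control array 3 alone the lens median at 48 hpf was 0.652 of the full value for MES particles and 0.0834 for TMAT particles. That is between the bounds for MES and below them for TMAT particles. At 24 hpf it was 0.0588 and −0.0065, near 0 for both. A difference between the control arrays therefore stays open too. A direct effect of the particles on the lens stays open as untested.

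At 24 hpf TMAT array 2, MES array 3 and control array 1 deviated from their groups together. If these pools had been at another stage, their deviations would follow the 24 to 48 hpf change across features with one sign. The correlations were −0.170, 0.0254 and 0.314, so the signs differed, which argues against a common shift in stage as the reason. Other technical explanations were not tested, and no biological explanation was tested.

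Other splits of the same arrays were fitted in the same way. For MES particles at 48 hpf 1 of 10 splits, the real one, gave as many calls as 2138, and the highest other gave 0. For 48 against 24 hpf in controls 1 of 10 splits, the real one, gave as many as 9942, and the highest other gave 1514. With 0 real calls, which every split reaches by construction, 10 of 10 splits gave as many for TMAT particles at 24 hpf (highest other 2025), for MES particles at 24 hpf (0), for TMAT particles at 48 hpf (0) and for TMAT against MES particles at 24 and 48 hpf (0 and 0). For these comparisons of 3 against 3 arrays, 10 splits are too few for a share under 0.05. The split with 2025 calls set control arrays 1 and 2 with TMAT array 2 against control array 3 with TMAT arrays 1 and 3 at 24 hpf. It points to a structure of the samples.

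For the change of the TMAT effect between ages the real count was 0, which 100 of 100 splits reach by construction, and the highest other had 3630. For any particle effect at 24 hpf the real count was also 0, reached by 100 of 100 splits, with a highest other of 5155. A real count of 0 leaves no call for these splits to test. For the MES interaction 2 of 100 splits reached the real count of 1, with a highest other of 355, and for any particle effect at 48 hpf 2 of 100 reached 696, with a highest other of 1264, so for both the share was under 0.05, without correction over the 11 results split in this way. These shares do not exclude chance. They come from a sample of the possible splits, with the real one counted. The control arrays also varied more than the exposed ones, so the arrays could not be swapped freely between groups. Neither count is stable. The 1 call of the MES interaction (adjusted p = 0.0487) is lost with median-centring or an intensity trend and without 10 of the 12 single arrays, and the 696 of the F test fall to 0 with arrays of one age, with the random-probe covariate and without 6 of the 9 single arrays, and to 2 without TMAT array 1. Splits with 355, 3630 and 5155 calls, far above the real counts, point to a structure of the samples. The splits do not tell a particle effect from another difference between the control and the exposed arrays.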

How the results depend on the processing

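The tests chosen only after the data were seen were gene-by-gene array weights, the fit without control arrays 1 and 2 of both ages, an unadjusted p of 0.05 with no limit on fold, the lens list without 3 crystallins, the random-probe level as a covariate and the axis over all features. Where a value moved below, the cause was not tested unless a reason is given.

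The count of calls between ages in controls, 9942, stayed within 1.5 times of that value with repeated quantile normalization (10629), median-centring (10565), the 25% of features with the lowest mean left out (9235), an intensity trend (9935), the random-probe covariate (9858) and each control array left out in turn (6876 to 12655). Counts for MES particles at 48 hpf stayed within 1.5 times of 2138 with repeated quantile normalization (2614, of which 2082 were the same features), median-centring (2017, 1909 the same), an intensity trend (2071, 1990 the same), arrays of one age (2599, 1625 the same) and the 25% left out (1590, 1584 the same). Of 78 genes taken by the naming rule for MES particles at 48 hpf 27 were called. Of these 27 calls 0 were lost with repeated quantile normalization and 3 with median-centring, and all 27 were lost with the ordinary statistic, the random-probe covariate, control arrays 1 and 2 left out together, and control array 1, control array 2, MES array 1 or MES array 2 left out alone. Of 50 calls among 77 such genes between ages, 1, 3 and 37 were lost with repeated quantile normalization, median-centring and the ordinary statistic. The balance for MES particles at 48 hpf, 1437 higher and 701 lower, was 1543 and 474 with median-centring, and it turned to 9121 and 15801 with default and 7038 and 12065 with gene-by-gene array weights. Signal over background limits what faint features can show, since the random probes read 78.8 to 169 and no mismatch or present call was used here. One-age fits cannot be run for the interactions or for the contrast between ages, which need both ages.

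Filters, scaling and variance models moved other counts. Leaving out the 50% of features with the lowest mean gave 555 calls for MES particles at 48 hpf, all 555 among the 2138, with 2 for the MES interaction, 6051 between ages in controls and 2 by the F test at 48 hpf; fewer features were tested. Repeated quantile normalization gave 1184 by that F test, and arrays of one age gave 0. The MES interaction had 0 calls with median-centring and 0 with an intensity trend. The ordinary statistic, which has fewer degrees of freedom, called 1 feature for TMAT and 0 for MES particles at 48 hpf, 0 for the MES interaction and 497 between ages.

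Array weights by limma's default method did not converge and gave control array 1 at 48 hpf a weight of 213. Calls were 316 for TMAT particles at 24 hpf, 20401 for TMAT and 24922 for MES particles at 48 hpf, 8 between the particles at 48 hpf, 10784 and 13294 for the TMAT and MES interactions, 21694 between ages and 26025 by the F test at 48 hpf. Under these weights cfbl turned to −0.29 for MES particles at 48 hpf and c3a.2 to −0.71 between ages. Gene-by-gene weights, with 6.39 for the same array, gave 14393 (TMAT) and 19103 (MES) at 48 hpf, 5 between the particles at 48 hpf, 4178 and 7626 for the interactions and 18039 by the F test at 48 hpf.

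Looser thresholds raised counts by construction. At an unadjusted p of 0.05 and 1.5-fold there were 1910 (TMAT) and 1221 (MES) features at 24 hpf, 6984 and 8125 at 48 hpf, 19 and 511 between the particles at 24 and 48 hpf, and 2769 and 5956 for the TMAT and MES interactions. With no limit on fold these were 2242, 1459, 7519, 8721, 37, 590, 2772 and 5960 in the same order. At an adjusted p of 0.1 there were 1482 for TMAT and 4345 for MES particles at 48 hpf and 2385 by the F test. At an unadjusted p of 0.05 in both particles the overlap was 805 features at 24 hpf and 5555 at 48 hpf.

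Without control arrays 1 and 2, which leaves 1 control array per age assumed to vary like the other groups, there were 0 calls for MES particles at 48 hpf, 0 for the MES interaction, 0 by the F test at 48 hpf and 2239 between ages. The random-probe covariate gave 0 calls for MES particles at 48 hpf, 0 for the MES interaction and 0 by the F test. With each array left out in turn the counts ran from 0 to 6310 for TMAT and from 0 to 6260 for MES particles at 48 hpf, from 0 to 1800 for the MES interaction and from 0 to 4895 by the F test at 48 hpf.

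The combined table with its columns as labelled gave 0 calls for MES particles at 48 hpf, 0 for the MES interaction, 0 between ages and 0 by the F test at 48 hpf, as its construction explains, since 16 of its 18 columns held the values that the per-array tables give to another sample. For agent, the labels of the per-array tables were taken as right. For MES particles at 48 hpf it turned rises into −0.49 for crygm2a, −2.08 for crygm2d4, −0.075 for crygm2b, −0.053 for avp, −0.21 for npffl, −0.33 for msrb2, −0.49 for tas2r200.1, −0.12 for xkr4 and −0.24 for zp3.2. It turned falls into 0.23 for sema6d, 0.017 for pmaip1, 0.29 for rnf114, 0.59 for vgll2a, 0.0037 for phlda1, 0.27 for kcnj11, 0.016 for lrrc30a and 0.62 for ppox. Between ages 5 genes turned, among them rhcga to −0.41, ank1a to −0.10, rorca to −0.35 and per3 to −0.024.

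Of the list calls by camera at a preset correlation, 0 of 2 were called for MES particles at 24 hpf with an estimated correlation, 0 of 2 for TMAT and 0 of 1 for MES particles at 48 hpf, 0 of 1 and 0 of 2 for the TMAT and MES interactions and 1 of 4 between ages. The fry test, directional and mixed, called 0 and 0 lists for MES particles at 24 hpf, 0 and 0 for TMAT particles at 48 hpf, 0 and 0 between the particles at 48 hpf, 0 and 0 for each interaction, and 10 and 13 between ages. With MES particles at 48 hpf the directional fry test did call the neuronal list, as given above. Without control arrays 1 and 2 there were 0 lists for MES particles at 24 hpf, 0 for TMAT and 0 for MES particles at 48 hpf and 0 for each interaction, and the lens list with MES particles at 24 hpf turned direction (adjusted p = 0.947). Without the 3 crystallins 1 list was called for TMAT particles at 24 hpf, 1 for TMAT and 0 for MES particles at 48 hpf. With each array left out in turn the number of lists ran from 0 to 1 for TMAT and 0 to 3 for MES particles at 24 hpf, 1 to 3 for TMAT particles at 48 hpf, 1 to 2 between the particles at 48 hpf, 1 to 2 for each interaction and 2 to 5 between ages. The lens adjusted p with MES particles at 24 hpf then ran from 0.000456 to 0.884, the latter with the direction turned.

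On the developmental axis the TMAT score at 24 hpf was −0.0408 with the 500 features of largest change, and it ran from −0.0902 to 0.0853 with each array left out. The MES score at 48 hpf ran from −0.0149 to 0.0323.

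With the replicate number as a replicate block within each age there were 0 calls for MES particles at 48 hpf, 0 for the MES interaction, 0 by the F test at 48 hpf and 4300 between ages (2492 higher and 1808 lower), and camera with the block called 2 lists between ages. All 27 named calls for MES particles at 48 hpf were absent from that fit. The correlations of deviations gave no sign that the numbers pair the arrays. Of 18 same-number pairs 5 had a correlation over 0.1 and 10 were below 0 (−0.731 to 0.504), against −0.732 to 0.759 for other pairs. Deviations of whole arrays could hide a pairing, so these values cannot set the block fit aside. As a hint from the data, 1 of 18 arrays correlated best with its own number in both other groups.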

Other observations

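Of 4 circadian clock genes, too few for a list test, 3 rose between ages in controls. With MES particles their values were positive at 24 hpf (median 0.60, 4 of 4) and negative at 48 hpf (median −0.55, 4 of 4), with TMAT particles 3 of 4 were positive at 24 hpf (median 0.49) and 0 of 4 at 48 hpf (median −0.68). The MES effect changed between ages by −1.63 ± 0.63 SE for rorca, −1.50 ± 0.58 for per3, −1.50 ± 0.67 for per1b and −0.47 ± 0.48 for hlfa. Adjusted over the list alone rorca and per3 passed (adjusted p = 0.0398 for both), and over all features 0 passed (adjusted p from 0.232 to 0.631). The time of day at which embryos were collected is not given in the sources used here, and no explanation was tested.

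Between 24 and 48 hpf in controls, further lists moved without a call by camera. Of 12 genes of cartilage, fin and extracellular matrix 3 rose and 0 fell (median 0.66, 11 of 12 positive, camera adjusted p = 0.164, fry adjusted p = 6.53e-05), among them matn3a (4.21 ± 0.25 SE) and ucmab (0.93 ± 0.25). Of 6 genes of yolk and lipid transport 2 rose, the apolipoprotein apoda.1 (3.00 ± 0.36) and the lipoprotein receptor ldlra (2.15 ± 0.33), with a camera adjusted p of 0.277 and a fry adjusted p of 0.00559. Of 8 red blood cell genes 2 fell and 1 rose (median −0.21, camera adjusted p = 0.207, fry adjusted p = 0.00103), the falls being those of the embryonic globin hbbe3 (−1.83 ± 0.26) and blf (−2.71 ± 0.24).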
